A study of Rattus norvegicus with 12 samples.

How the data were processed

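The samples were uterine endometrial stromal cells, the connective tissue cells of the uterine lining, grown from the uteri of pregnant rats around the time embryos implant. The rats carried a reporter in which the mouse Per2 promoter drives a short-lived luciferase. Per the labels' protocols, the cells were kept in serum-free medium with progesterone and then given a short pulse of dexamethasone, a glucocorticoid that sets the phase of the clock in cultured cells. RNA was taken 30, 36, 42 and 48 h after this synchronization, with 3 samples at each time. The labels do not say whether the 3 samples of a time came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The extraction protocol in the labels describes a blood RNA kit with globin removal, although the cells were cultured stromal cells. Samples with RNA interference against Bmal1, which the series also describes, were not analysed here.

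Each of the 12 samples was hybridised with Cy3 to 1 array of a 1-colour Agilent rat design with 30367 non-control probes. Per the file headers, the deposited scanner files were made with Feature Extraction 10.7.1.1 (protocol GE1_107_Sep09), while the submitters' processing notes name version 9.5.1.1. The spot intensity used here was, per the file headers, background-subtracted and detrended within its array, with no scaling between arrays, and the mean and background pixel intensities of the same spots served 1 alternative. The deposited value table holds 1 intensity per probe on a linear scale and correlated with the log2 scanner intensities at 0.9999 or more across probes of each array. Every column of it had a median of 48.8 and the same lowest and highest values, 3.37 and 183497, as after quantile normalization. Any offset behind it, and the software used, are not given in the sources used here. Probe coordinates in the files are on rat build rn4 and were left as given.

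For the values reported here, log2 intensity was reduced by the 75th percentile of its array over non-control spots. Control spots and spots flagged as outliers were left out, and spots of a probe were averaged. A probe entered the test when it was well above background on all 3 arrays of at least 1 time, which left 18036 probes. The brightest probe stood for a gene, which gave 15727 genes, 11150 of them with a symbol that is no placeholder. An accession was matched to a current symbol, from the GRCr8 RefSeq table used for names alone, for 59.3% of the probes (18006), and the name in the file was kept otherwise. Bmal1 is listed as Arntl in the files, Bmal2 as Arntl2, Ciart as RGD1566380, Or52e19 as Olr87, Pimreg as Fam64a, Adgrf5 as Gpr116, Tmem252 as RGD1359349, Sapcd2 as LOC680531, Msmo1 as Sc4mol, Mt1 as Mt1a, Gsta1 as Gsta3 and Bcl2a1 as Bcl2a1d. A probe that was not well above background on any array of a time has only a bound there. Its change is given as "at least N-fold", the brighter group's mean over the dimmer group's mean of, on each array, the higher of the probe's own signal and the lowest signal among probes well above background.

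Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 12 arrays in 1 model and Benjamini-Hochberg adjustment at 0.05. An F-test asked which genes changed over the 4 times. Contrasts compared 42 h with 30 h and 48 h with 36 h, which are the components of a 24 h rhythm sampled in this way, and each time with the time before it. SE denotes the standard error of a log2 change from this model, and SD the spread of 3 arrays. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists of a contrast, and again with an estimated correlation. The lists were core clock, E-box and D-box driven clock output, decidualization and implantation, growth factors, apoptosis, glucocorticoid response, cell cycle, cholesterol synthesis, hypoxia and glycolysis, amino acid and ER stress response, interferon response, inflammatory cytokines, extracellular matrix, heat shock, immediate early, NRF2 response, cytosolic ribosomal proteins, mitochondrial respiration, and markers of endometrial stroma, epithelium, endothelium, leukocytes, smooth muscle and red cells. Lists, contrasts and the rule for named genes were fixed before the data were examined. For each 12 h contrast the rule took every measured core clock gene, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the times, and up to 4 called members of every other list by size, or the 2 largest where none was called. For each 6 h step it took the 3 largest rises and the 3 largest falls. Genes with placeholder symbols were not named. The replication genes Mcm2 to Mcm7 and Pcna, and Rrm2, Inhba, Klf9, Bok, Junb, Col1a2 and Timp1 at 48 h against 36 h, lie outside the rule and were named after their values were seen.

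The arrays lay on 3 slides of 4. Slide 1 held the 30 h samples and 36 h replicate 1, slide 2 held 36 h replicates 2 and 3 and 42 h replicates 1 and 2, and slide 3 held 42 h replicate 3 and the 48 h samples. Slide thus ran nearly along with time. Values with slide as a block are therefore given, and 6 h steps are also given within the slide that holds both times. Alternatives changed the background correction, the scaling, the filter on dim probes, the choice of probe, array weights, the threshold, the slide or replicate number as a block, and the arrays included. The background alternative, normexp, added an offset of 50 to the intensities. This draws log2 changes of dim probes toward 0, so smaller values and lost calls of such probes there are in part by construction. On simulated data with 15727 genes, the contrast of 42 h with 30 h recovered 43.3% of 67 genes changed by 0.5 on the log2 scale, 88.1% of 67 changed by 1 and 93.9% of 66 changed by 2. The contrast of 48 h with 36 h recovered 46.3%, 89.6% and 95.5% of as many genes. False calls were 10 and 6 of 160 calls in turn. The simulated values were independent between genes and arrays and held no slide effect, so these rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.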

Results

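Gene expression was measured in rat uterine endometrial stromal cells on 12 arrays, 3 for each of the times 30, 36, 42 and 48 h counted from the dexamethasone pulse. Between 62.7% and 69.4% of the spots of an array were well above background, and no spot was saturated. The 75th percentile of log2 intensity lay between 9.25 and 9.63 at 30 h, between 9.34 and 9.95 at 36 h, between 9.29 and 10.01 at 42 h and between 9.92 and 10.07 at 48 h. Correlations across the genes tested were 0.986 to 0.997 between arrays of the same time and 0.986 to 0.994 between times. On principal component 1, the main axis of spread between arrays (32.2% of variance), 42 h replicate 3 stood at 25.81. The 48 h arrays of its slide stood at 23.38 to 25.39, and 42 h replicates 1 and 2 at -18.26 and 1.37. By contrast, 36 h replicate 1 stood at 3.19 while the 30 h arrays of its slide lay below 0. At 75th percentiles of 9.95 and 9.81, 36 h replicate 1 and 42 h replicate 2 stood far below 48 h replicate 2, at 9.92. Brightness alone thus did not set the place on this axis, though the parts of slide, time and brightness were not separated. The number of arrays, 3 per time, limits the precision.

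The series asked which genes follow the clock in these cells. Bmal1, the activator at the centre of the loop, rose from -1.54 ± 0.06 (SD, n = 3) at 30 h to -0.76 ± 0.18 at 36 h and was back at -1.43 ± 0.05 at 48 h, in log2 units relative to the array's 75th percentile. Npas2, a paralogue of Clock whose product pairs with that of Bmal1, took a like course, with -0.32 ± 0.01 at 30 h, 0.22 ± 0.15 at 42 h and -0.50 ± 0.08 at 48 h. Per2, a repressor of that activator, went the other way, from -2.37 ± 0.17 at 30 h to -3.86 ± 0.14 at 42 h and -2.59 ± 0.12 at 48 h. The output factor Dbp was lowest at 36 h, at 1.20 ± 0.24 against 2.38 ± 0.16 at 30 h, and the repressor Nr1d1 went from -3.76 ± 0.24 at 36 h to -1.81 ± 0.23 at 48 h. By limma's F-test these genes changed over time, with adjusted p = 0.00817 for Bmal1, 0.00186 for Npas2, 0.000569 for Per2, 0.00441 for Dbp and 0.00454 for Nr1d1. In all, 1087 of 15727 genes changed over time, and 4613 had an unadjusted p under 0.05. Most changed genes peaked at an end of the series, 393 at 30 h and 549 at 48 h, against 85 at 36 h and 60 at 42 h. The count was 295 with slide as a fixed block and 123 with slide as a random block, and it ranged from 313 without 48 h replicate 3 to 2400 without 42 h replicate 3, with 10 of the 12 arrays moving it by over 1.5 times.

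**Figure D1:**
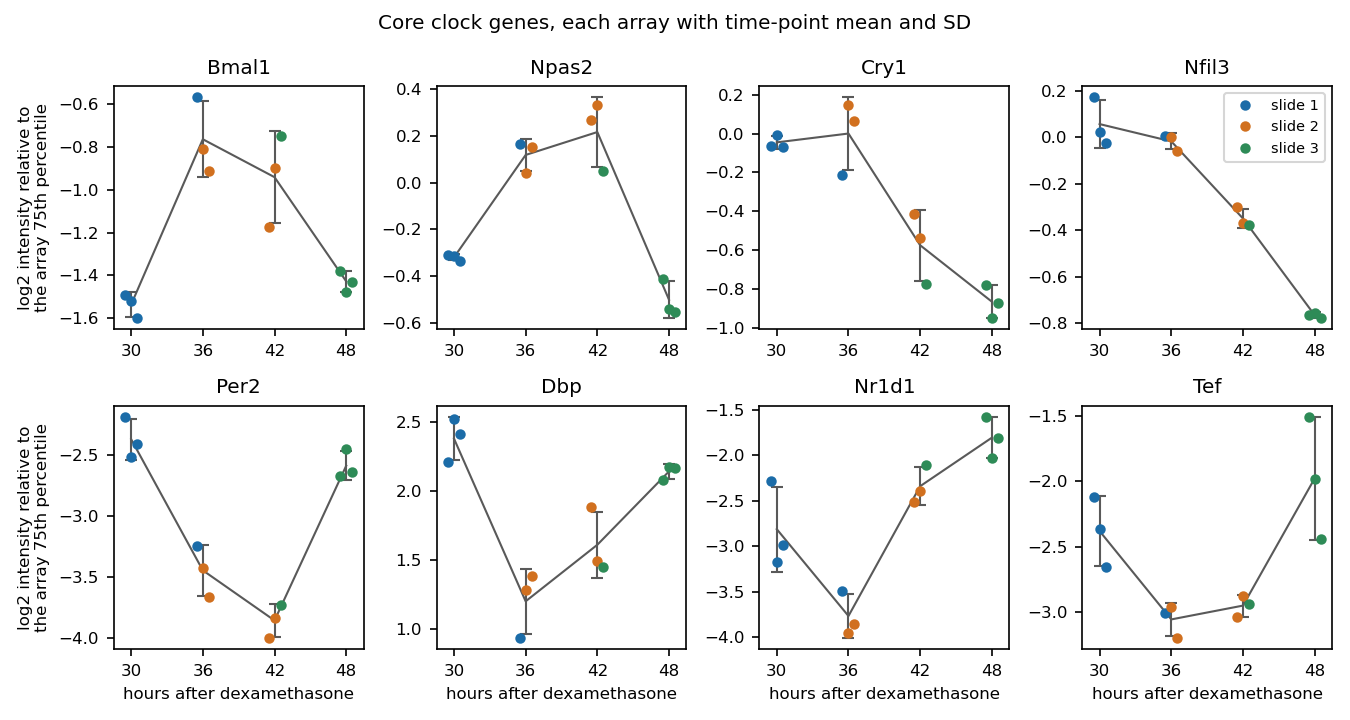
Log2 intensity of 8 core clock genes, relative to the 75th percentile of the array, against hours after dexamethasone. Points are single arrays coloured by slide, lines and bars are the mean and SD of 3 arrays. Per2 is lowest at 42 h (-3.86 ± 0.14) and Bmal1 is highest at 36 h (-0.76 ± 0.18).

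At 42 h against 30 h, Per2 fell by 1.49 (SE 0.13, adjusted p = 0.000885), the widely clock-driven factor Dbp by 0.77 (SE 0.14, adjusted p = 0.031) and the cell cycle kinase Wee1 by 0.64 on the log2 scale. Cry1 fell by 0.53, Nfil3 by 0.41 and Bhlhe40 by 0.32, while Bmal1 rose by 0.59 (SE 0.11, adjusted p = 0.0359) and Npas2 by 0.54 (SE 0.08). The mitotic kinesin Kif11 rose by 0.90 (SE 0.10), the kinase Melk by 0.88, the DNA topoisomerase Top2a by 0.80 and Aurkb, a mitotic kinase, by 0.78. In all, 133 genes rose and 110 fell by limma with n = 3 per time, and 2296 had an unadjusted p under 0.05. The probes of these clock genes lie on rn4 chromosome 9 at 90645610 to 90645669 for Per2, chromosome 1 at 96178423 to 96178482 for Dbp, chromosome 1 at 171161969 to 171162028 for Bmal1 and chromosome 9 at 38433884 to 38433943 for Npas2.

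Among the largest other rises, the matrix protein gene Tnn rose by 1.55, Krt15 by 1.18, the mitotic kinase Pbk by 1.03, the condensin subunit Ncaph by 1.00, and Dclk3, well above background on 1 array of 30 h, by 1.00. Nup210 rose at least 2.14-fold, Calca at least 1.65-fold, Tmem176a at least 1.23-fold and Neurod2 at least 1.11-fold, and Neurod2 and Tmem176a were well above background on 1 array of 42 h each. Rnf152 was not well above background on any array of either time. With normexp background correction Nup210 stood at 0.25, Calca at 0.08, Tmem176a and Neurod2 at 0.05, Dclk3 at 0.13 and Rnf152 at -0.06, and none of these passed. The offset of 50 in that correction draws changes of such dim probes toward 0 by construction. Tnn at 0.47 and Pbk at 0.37 did not pass there either, and Krt15 passed at 0.49. The largest falls besides Per2 were the olfactory receptor gene Or52e19, lower at least 2.42-fold, and Myh15, lower at least 1.64-fold. Tspan33 fell by 1.28, Hsd11b2, whose enzyme inactivates glucocorticoids, by 1.25, the growth factor gene Gdf10 by 1.22 and Bmal2, a paralogue of Bmal1 well above background on 1 array of 42 h, by 1.15. Tmem252 fell by 1.11, Plcxd3 by 1.07 and Sult1a1 by 1.06. With normexp Or52e19 stood at -0.70, Myh15 at -0.52 and Bmal2 at -0.51 without passing, and Tspan33 at -0.84, Tmem252 at -0.68 and Plcxd3 at -0.64 passed.

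By list, 15 of 38 cell cycle genes rose and none fell at 42 h against 30 h, and 25 rose when adjusted over the list alone. Their median log2 change was 0.44 (camera adjusted p = 5.01e-28, and adjusted p = 0.0543 with an estimated correlation). With slide as a fixed block it was 0.35 (adjusted p = 4.08e-06), and within slides it was 0.07 from 30 to 36 h and 0.37 from 36 to 42 h. Of 12 E-box and D-box driven outputs, 4 fell (Per2, Dbp, Wee1 and Bhlhe40) and none rose, and 6 fell adjusted over the list alone. Their median change was -0.55 (adjusted p = 8.38e-06, and adjusted p = 0.0543 with an estimated correlation), and -0.44 with slide as a block (adjusted p = 0.0171). Within slides the median was -0.56 from 30 to 36 h and 0.02 from 36 to 42 h. The core clock list had 2 rises and 5 falls among 21 genes, 2 and 8 adjusted over the list alone, with a median of -0.41 (adjusted p = 0.00663, adjusted p = 0.139 with an estimated correlation) and -0.38 with slide as a block (adjusted p = 0.00974). It shares most members of the E-box and D-box list, Per2, Dbp and Bhlhe40 among them, so these shifts are not separate results. Values of the core clock genes that did not pass were -0.16 for Clock, -0.52 for Per3, -0.72 for Cry2, 0.47 for Nr1d1, -0.77 for Nr1d2, -0.13 for Rora, -0.46 for Rorb, -0.57 for Tef, 0.12 for Csnk1d, -0.03 for Csnk1e, 0.04 for Fbxl3 and 0.04 for Timeless. Without 30 h replicate 1 these were -0.24 for Per3, -0.38 for Cry2, 0.73 for Nr1d1 and -1.43 for Nr1d2. Without 30 h replicate 2 they were 0.29 for Nr1d1 and -0.25 for Nr1d2. Per3 stood at -0.79 and Clock at -0.29 without 42 h replicate 1. Clock stood at -0.01 without 42 h replicate 3, and Rora at -0.04 without 30 h replicate 3 and -0.25 without 42 h replicate 2. Csnk1e, Fbxl3 and Timeless turned sign in 1 or more such fits. Nr1d2 was well above background on 1 array of 42 h and 2 of 30 h. Per1 was well above background on 1 array of 42 h and on none of 30 h, which leaves its change unmeasured. Ciart, which was not well above background at 42 h, was at least 1.77-fold lower without passing (adjusted p = 0.063), and its change was 0.07 with slide as a block. The calls were kept in 24 of 26 alternatives for Per2, 23 for Npas2, 21 for Nfil3, 12 for Dbp, 10 for Cry1, and 9 each for Bmal1 and Bhlhe40, with every sign kept.

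The hypoxia and glycolysis list had 1 fall among 28 genes, Ankrd37 (by 0.48), 5 falls adjusted over the list alone, and a median of -0.20 (camera adjusted p = 5.54e-06, adjusted p = 0.551 with an estimated correlation). Of 20 glucocorticoid response genes, the metallothionein gene Mt2A fell by 0.77 and the cell cycle inhibitor gene Cdkn1c by 0.40, and 6 fell adjusted over the list alone, with a median of -0.22 (adjusted p = 0.000782, adjusted p = 0.413 with an estimated correlation). With slide as a block the medians of these lists were -0.13 and -0.14, each at adjusted p = 0.159. No cholesterol synthesis gene passed among 24, with a median of -0.09 (adjusted p = 0.0199, adjusted p = 0.78 with an estimated correlation) and 0.02 with slide as a block, and Tm7sf2 stood at -0.51 and Pcsk9 at -0.43 (-0.18 without 30 h replicate 1). None of 17 leukocyte markers passed either, with a median of 0.09 (adjusted p = 0.0262, adjusted p = 0.78 with an estimated correlation) that turned to -0.09 with slide as a block. Of 39 growth factor genes, Gdf10 fell, Igf1 fell by 0.78 and Inhba rose by 0.47, and 5 rose and 3 fell adjusted over the list alone (median 0.02, adjusted p = 0.632). Of 45 apoptosis genes 1 rose, also 1 adjusted over the list alone (adjusted p = 0.407), Birc5 (by 0.69), which is also a cell cycle gene and codes for survivin. The cystine transporter gene Slc7a11, in the amino acid and NRF2 lists, fell by 0.68, the gelatinase gene Mmp9 by 1.05, Jun by 0.54 and the cytokine gene Tnf by 0.36. Each was the single call of its list. Medians were -0.07 for amino acid and ER stress (adjusted p = 0.137), 0.01 for NRF2 response (adjusted p = 0.663), 0.02 for extracellular matrix (adjusted p = 0.292), 0.01 for immediate early genes (adjusted p = 0.927) and -0.09 for inflammatory cytokines (adjusted p = 0.565). Adjusted over the list alone, 1, 2, 2, 1 and 2 of their genes fell, and 2 matrix genes rose.

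In the remaining lists no gene passed at 42 h against 30 h and no list shifted. The decidualization and implantation list had a median of -0.10 over 22 genes (adjusted p = 0.23), with Il11 at -0.46 (-0.10 without 30 h replicate 2) and Nr2f2 at -0.43. Medians were -0.17 for interferon response, where Rsad2 stood at 1.09 (0.63 without 30 h replicate 1) and Usp18 at -0.995 (-0.27 without 30 h replicate 3), -0.09 for heat shock, where Hspa4l stood at -0.60 and Bag3 at -0.57, and -0.03 for cytosolic ribosomal proteins. There Rpl32 stood at -0.19 (-0.05 without 42 h replicate 3 and -0.29 without 42 h replicate 1) and Rpl13 at -0.13 (-0.09 without 30 h replicate 1). The ribosomal list turned to 0.21 with slide as a block (adjusted p = 0.00974). Mitochondrial respiration had a median of 0.01, with Cox4i1 at -0.23 (-0.13 without 42 h replicate 3 and -0.36 without 42 h replicate 1, where it passed) and Ndufv2 at -0.21 (-0.13 and -0.32 without these arrays in turn). Marker medians were 0.04 for endometrial stroma, -0.06 for endothelium, 0.11 for epithelium, 0.05 for smooth muscle and 0.19 for red cells. The members furthest from 0 in stroma and endothelium were Lum at -0.91 (-0.27 without 30 h replicate 1, and well above background on 1 array of 42 h), Sox18 at -0.60 and Flt1 at -0.53 (-0.32 without 30 h replicate 1). For epithelium and smooth muscle they were Krt18 at 1.06 (0.46 without 42 h replicate 3 and 2.26 without 42 h replicate 2), Prss8 at 0.54 (0.35 without 42 h replicate 3 and 0.91 without 42 h replicate 2, where it passed), and Myh11 at 0.28 and Des at -0.23. Among red cell markers Epor was at least 1.27-fold higher without passing and Ahsp stood at 0.22 (0.13 without 30 h replicate 3). Among leukocyte markers RT1-Da was at least 1.07-fold higher without passing and C1qb stood at 0.42. Epor and RT1-Da were well above background on 1 array of 42 h each and on none of 30 h. Adjusted over the list alone, 1 decidualization gene rose and 1 fell, 2 heat shock genes fell, 1 smooth muscle marker rose and 1 fell, and 1 red cell marker rose. Median, mean and camera direction differed in sign for apoptosis, growth factors, immediate early genes and endometrial stroma.

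Blocking on slide, the contrast of 42 h with 30 h called 1 gene higher and 0 lower, though all 243 genes kept their sign, with a median change of 0.57 against 0.59 and a median SE of 0.16 against 0.09. With a median shift in place of the 75th percentile, 166 genes rose and 61 fell (73.1% higher against 54.7%), a fit of the 6 arrays alone called 0 genes, and leaving out single arrays gave 58 to 203 higher and 45 to 170 lower, with 36 h replicates 1 and 3 and 48 h replicate 2 the arrays that moved neither count by over 1.5 times. Of the 41 genes named with a call, 16 kept it in at most 12 of 25 or 26 alternatives. These were Neurod2, Nup210, Rnf152, Gdf10, Bmal2, Aurkb, Bmal1, Cry1, Dbp, Bhlhe40, Mt2A, Cdkn1c, Inhba, Ankrd37, Jun and Tnf. With normexp background correction Per2 stood at -0.88, Kif11 at 0.47 and Birc5 at 0.46, which passed, and Melk at 0.42 and Aurkb at 0.20, which did not. Npas2 stood at 0.30 as the mean of its probes and Tnf at -0.23 with slide as a block, neither of which passed.

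At 48 h against 36 h, Nr1d1 rose by 1.96 (SE 0.23, adjusted p = 0.00233), Tef by 1.08 (SE 0.21), Dbp by 0.94 (SE 0.14, adjusted p = 0.00821) and Per2 by 0.86 (SE 0.13, adjusted p = 0.00695). Bmal1 fell by 0.66 (SE 0.11, adjusted p = 0.0144), Npas2 by 0.62 (SE 0.08), Cry1 by 0.87, Nfil3 by 0.75 and Rorb by 0.62 on the log2 scale. Blocking on slide gave 1.75 for Nr1d1 (adjusted p = 0.0587) and 1.09 for Tef (adjusted p = 0.219), which did not pass, and -0.68 for Cry1 (adjusted p = 0.0266) and -0.70 for Nfil3 (adjusted p = 0.023), which did. The mitotic kinase Plk1 rose by 0.99 (SE 0.10), and Bub1, Cenpf and Cdc20, of the spindle checkpoint and kinetochore, rose by 0.87, 0.85 and 0.84. Psat1 and Phgdh, enzymes of serine synthesis, rose by 0.81 and 0.60, the mitochondrial folate enzyme gene Mthfd2 by 0.69 and Atf4, a regulator of amino acid genes, by 0.44. By limma, 535 genes rose and 458 fell with n = 3 per time, and 4822 had an unadjusted p under 0.05.

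Among the largest other rises, Tnn rose by 1.97, Srpk3, well above background on 1 array of 36 h, by 1.86 and Pimreg, a mitotic gene, by 1.46. Gas2l3 rose at least 1.63-fold, the class II histocompatibility gene RT1-Da at least 1.61-fold, Myh8 at least 1.20-fold and the macrophage receptor gene Cd163 at least 1.03-fold. The hyaluronan synthase gene Has2 and the apoptosis gene Hrk passed but were not well above background at 36 h, and their bounds did not reach 1. With normexp background correction Gas2l3 stood at 0.06, RT1-Da at 0.03, Myh8 at -0.07, Cd163 at -0.19, Has2 at -0.09, Hrk at 0.03 and Srpk3 at 0.68, and none of these passed. Tnn at 0.97 and Pimreg at 0.97 did. The largest falls were Rax, at least 2.67-fold, which stood at 0.32 with slide as a block, and Adgrf5, which was called but well above background on only 1 array of 48 h, so its size was not measured well. L1td1 was at least 1.47-fold and Myh15 at least 1.67-fold lower, each well above background on 1 array of 36 h. The kinase gene Sgk3 fell by 2.19, though without 36 h replicate 3 it stood at -1.45 and did not pass (adjusted p = 0.0526). Lrrc4 fell by 1.66, Cox8b by 1.53, Adra2a by 1.51, the growth factor gene Gdf5 by 1.43 and Mgll, whose enzyme breaks down monoglycerides and which was well above background on 1 array of 48 h, by 1.34. With normexp Rax stood at -1.01, Adgrf5 at -1.11, L1td1 at -0.86, Sgk3 at -1.24, Lrrc4 at -0.82 and Mgll at -0.68 without passing, and Myh15 at -0.73, Adra2a at -0.81 and Gdf5 at -0.68 passed.

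By list, 17 of 38 cell cycle genes rose at 48 h against 36 h and 1 fell, the replication helicase gene Mcm5 (by 0.62, a call kept in 9 of 26 alternatives), with 23 and 4 adjusted over the list alone. Their median change was 0.50 (camera adjusted p = 1.02e-07, adjusted p = 0.459 with an estimated correlation) and 0.34 with slide as a block (adjusted p = 0.0539). Within slides it was 0.37 from 36 to 42 h and 0.01 from 42 to 48 h. Of 12 E-box and D-box driven outputs 4 rose (Nr1d1, Tef, Dbp and Per2), also 4 adjusted over the list alone, with a median of 0.58 (adjusted p = 0.000172, adjusted p = 0.138 with an estimated correlation), 0.57 with slide as a block (adjusted p = 0.0399), and 0.02 and 0.42 within slides for the steps to 42 and to 48 h. Of 29 amino acid and ER stress genes 6 rose and 13 did so adjusted over the list alone, with a median of 0.14 (adjusted p = 0.000125, adjusted p = 0.385 with an estimated correlation), 0.31 with slide as a block (adjusted p = 0.044), and 0.13 and 0.17 within slides. No cytosolic ribosomal protein gene passed among 38, though 30 stood above 0, with a median of 0.19 (adjusted p = 0.000172, adjusted p = 0.822 with an estimated correlation) and 0.28 with slide as a block (adjusted p = 0.000155). Rpl24 stood at 0.52 and Rplp1 at 0.46, and within slides the list's medians were 0.14 and 0.16. Leukocyte markers had a median of 0.30 at the same contrast.

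**Figure D2:**
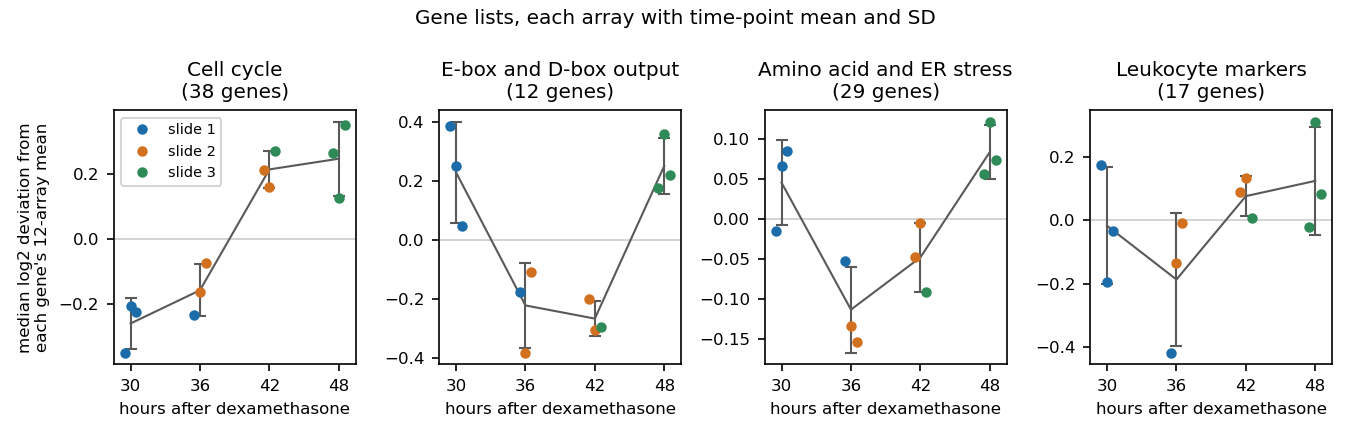
Median log2 deviation of the members of 4 gene lists from each gene's mean over 12 arrays, against hours after dexamethasone. Points are single arrays coloured by slide, lines and bars are the mean and SD of 3 arrays. The cell cycle medians of single arrays, over 38 genes, lie between -0.35 and -0.07 at 30 and 36 h and between 0.13 and 0.35 at 42 and 48 h.

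Of 17 leukocyte markers, 4 rose at 48 h against 36 h and 6 did so adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.000778, adjusted p = 0.822 with an estimated correlation) and 0.29 with slide as a block (adjusted p = 0.166). These were RT1-Da and the complement genes C1qc (by 0.83), C1qb (by 0.64) and C1qa (by 0.63), and the list's medians within slides were 0.19 and 0.18. Of 19 NRF2 response genes, the glutathione transferase genes Gsta1 and Gstp1 rose by 0.85 and 0.44, and 7 rose adjusted over the list alone, with a median of 0.25 (adjusted p = 0.0004, adjusted p = 0.618 with an estimated correlation) and 0.19 with slide as a block (adjusted p = 0.502). Of 23 immediate early genes 5 rose, Egr1 by 0.75, Nr4a1 by 0.62, Egr2 by 0.61, Ier3 by 0.58 and Junb by 0.40, and 9 rose and 1 fell adjusted over the list alone. Egr2 stood at -0.03 with normexp background correction, and the list had a median of 0.10 (adjusted p = 0.00418, adjusted p = 0.188 with an estimated correlation) and 0.22 with slide as a block (adjusted p = 0.192). Of 40 extracellular matrix genes 5 rose and 1 fell, 11 and 2 adjusted over the list alone, with a median of 0.08 (adjusted p = 0.0395, adjusted p = 0.884 with an estimated correlation) and 0.16 with slide as a block (adjusted p = 0.502). The protease genes Mmp10 and Mmp13 rose by 1.38 and 1.00, Bgn, for a proteoglycan, by 0.54 (0.05 as the mean of its probes, without passing), the collagen gene Col1a2 by 0.53 and Timp1 by 0.34, while Mmp9 fell by 0.90.

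The remaining lists did not shift at 48 h against 36 h. Growth factor genes went both ways, with 2 rises and 3 falls among 39, as Gdf5, Igf1 (by 0.90) and Bmp7 (by 0.84) fell and the activin subunit genes Inhbb and Inhba rose by 0.71 and 0.70, and 5 rose and 4 fell adjusted over the list alone (median 0.03, adjusted p = 0.686). Of 45 apoptosis genes 3 rose and 2 fell, 6 and 2 adjusted over the list alone (median 0.09, adjusted p = 0.164). Birc5 rose by 0.83, Bcl2a1, which stood at -0.14 with normexp, rose at least 1.38-fold, Hrk passed, Dapk1 fell by 0.40 and Bok by 0.37. Glucocorticoid response had 1 rise, Klf9 (by 0.30), and 4 falls among 20, the metallothionein genes Mt2A (by 1.14) and Mt1 (by 0.93), then Cdkn1c (by 0.63) and Errfi1 (by 0.54), with a median of -0.07 (adjusted p = 0.623). Decidualization and implantation had 1 rise, Wnt4 (by 0.25), and 3 falls, the stromal transcription factor gene Hand2 (by 0.35), Fkbp4 (by 0.33) and Des (by 0.23), with a median of -0.01 (adjusted p = 0.726). The core clock list had 4 rises and 5 falls, 5 and 7 adjusted over the list alone, and a median of 0.10 (adjusted p = 0.766). Adjusted over the list alone, 2 rose and 4 fell in glucocorticoid response and 2 rose and 3 fell in decidualization.

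Core clock genes that did not pass at 48 h against 36 h stood at -0.53 for Clock, 0.17 for Per3 (0.04 without 36 h replicate 2 and 0.40 without 36 h replicate 3), -0.95 for Cry2 (-0.60 without 36 h replicate 3 and -1.46 without 36 h replicate 1, adjusted p = 0.0282), and -0.32 for Rora (-0.20 without 36 h replicate 3). They stood at 0.13 for Bhlhe40, 0.98 for Ciart (2.16 with slide as a block, adjusted p = 0.0303, 0.47 without 36 h replicate 3, and 1.65 without 36 h replicate 1, adjusted p = 0.0132), 0.13 for Csnk1d, 0.05 for Csnk1e (-0.08 without 36 h replicate 1 and 0.19 without 36 h replicate 2), 0.10 for Fbxl3 (0.06 without 36 h replicate 3 and 0.15 without 36 h replicate 1) and -0.35 for Timeless. Per1 and Nr1d2 were not well above background on any array of 36 h and reached no bound, and Ciart was above it on 1 array of 36 h. In heat shock Bag3 fell by 0.58 and Dnaja1 by 0.20 (median -0.05), in hypoxia and glycolysis Pdk1 fell by 0.51 and Kdm3a by 0.28 (median 0.01), and in cholesterol synthesis Msmo1 rose by 0.47 (median 0.15, adjusted p = 0.11). Ndufa9 fell by 0.42 in mitochondrial respiration (median -0.01). Interferon response had a median of 0.11, with Ifit3 at 0.82 (0.48 without 48 h replicate 1, further from 0 without 48 h replicate 2) and Rsad2 at 0.43 (-0.05 and 1.18 without these arrays in turn). Inflammatory cytokines had -0.06, with Csf3 at -0.78 and Ccl20 at -0.56 (-0.02 without 36 h replicate 3 and -0.98 without 48 h replicate 2), and no gene was called in either list. The endothelial marker Kdr rose by 0.78 (median 0.06). Medians of the other markers were -0.08 for endometrial stroma, where Hand2 fell, -0.04 for smooth muscle, where Des fell, 0.03 for epithelium and 0.08 for red cells. Of epithelium, Krt18 stood at -0.93 (-0.55 without 36 h replicate 2 and -1.46 without 36 h replicate 1) and Spint2 at 0.27. Of red cells, Klf1 was not well above background at 36 h and Epor stood at -0.31 (-0.02 without 36 h replicate 3 and -0.53 without 36 h replicate 2). Median, mean and camera direction differed in sign for core clock, hypoxia, epithelium, smooth muscle and growth factors.

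In the fit blocked on slide, 520 genes rose and 44 fell at 48 h against 36 h, and 75 of the 993 calls were kept. Of the 993 genes 991 kept their sign, with a median change of 0.39 against 0.47 and a median SE of 0.15 against 0.09. Counts ranged from 93 up and 42 down without 36 h replicate 2 to 1473 up and 1371 down without 36 h replicate 1, and each of the 12 arrays, left out alone, moved 1 or both counts by over 1.5 times. Of the 77 genes named with a call, 21 kept it in at most 12 of 25 or 26 alternatives. These were Srpk3, Has2, Hrk, Cd163, Rax, Adgrf5, L1td1, Sgk3, Mgll, Dapk1, Msmo1, Wnt4, Des, Mmp13, Errfi1, Dnaja1, Egr2, Ndufa9, Mcm5, Klf9 (11 of 26) and Timp1 (8 of 26). With normexp background correction Nr1d1 stood at 1.12 and Per2 at 0.43, which passed. Tef at 0.58, Cenpf at 0.32, C1qc at 0.34, Mmp10 at 0.73, Mmp13 at 0.63, Junb at 0.18, Errfi1 at -0.35, Fkbp4 at -0.21, Des at -0.09 and Dnaja1 at -0.08 did not pass there. With slide as a block Bmp7 stood at -0.34, Bag3 at -0.37, Pdk1 at -0.33, Dapk1 at -0.21, Bok at -0.23, Timp1 at 0.21 and Klf9 at 0.51 without passing. Atf4 at 0.68 and Mgll at -2.08 passed in that fit. With the brightness covariate Bmp7 stood at -0.48, Bag3 at -0.35, Dapk1 at -0.23, Errfi1 at -0.30 and Msmo1 at 0.31 without passing, and Pdk1 passed at -0.30.

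The 12 h contrasts compare different arrays but take each gene's spread from the same fit of 12 arrays, and 142 genes were called in both. A gene with a small spread is favoured in both contrasts, so the overlap is not one of independent tests. Of these, 87 were higher in both and 51 lower in both. Slide runs along time in both contrasts. Blocked on slide, 42 h against 30 h kept 0 of its 243 calls. All 243 genes kept their sign there, at a median change of 0.57 against 0.59 with a median SE of 0.16 against 0.09, so slide is neither shown nor excluded as a source of the overlap. The other 4 of the 142 changed in opposite directions, and all were core clock genes, namely Bmal1, Npas2, Per2 and Dbp. Of the 142 genes 6 were core clock genes, and Cry1 and Nfil3 fell in both contrasts. The opposite directions were noticed after the values were seen. Blocked on slide, the changes at 42 h against 30 h and at 48 h against 36 h were 0.79 and -0.85 for Bmal1, 0.69 and -0.34 for Npas2, -1.25 and 0.78 for Per2, and -1.09 and 1.05 for Dbp. None of the 4 passed there at 42 h against 30 h (adjusted p = 0.135, 0.087, 0.0947 and 0.162), and at 48 h against 36 h Bmal1 and Dbp passed (adjusted p = 0.0261 and 0.0396) while Npas2 and Per2 did not (adjusted p = 0.133 and 0.0842). Fitted as a 24 h rhythm, which the 18 h sampled cannot test, Bmal1 peaked at 38.8 h and Npas2 at 38.7 h, Cry1 at 33.9 h and Nfil3 at 34.1 h, and Nr1d1 at 47.1 h, Tef at 49.9 h, Dbp at 50.6 h and Per2 at 52 h. These times follow from the 12 h contrasts and the assumed period, and those after 48 h lie past the last sample. A gene that fell in both contrasts gets an early peak by construction.

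The 6 h steps were fitted too, without a test of the difference between steps. From 30 to 36 h, 3 genes rose and 7 fell. Dbp fell by 1.18 (SE 0.14, adjusted p = 0.0258), Per2 by 1.08 (SE 0.13, adjusted p = 0.0236) and Cyp26b1, whose enzyme degrades retinoic acid, by 1.01, while Dclk3 rose by 0.86 and Fibin by 0.54. Within slide 1 Dbp stood at -1.45, Per2 at -0.87 and Bmal1 at 0.97. From 36 to 42 h, 40 genes rose and 14 fell, with Nr1d1 up by 1.43 (SE 0.23, adjusted p = 0.0329), Pimreg by 0.94 and Sapcd2 by 0.87, and with Tmem252, Car5b and Plekhg4 down by 0.81, 0.73 and 0.71 (all n = 3, limma). Of the cell cycle genes 6 rose at this step. Within slide 2 Nr1d1 stood at 1.45. From 42 to 48 h, 22 genes rose and 8 fell. Per2 rose by 1.27 (SE 0.13, adjusted p = 0.0168), Dnase1l3 by 1.42 and the cartilage matrix gene Cilp by 1.31, while Mt2A fell by 1.12, Add3 by 0.83 and Npas2 by 0.72. Within slide 3 Per2 stood at 1.15 and Npas2 at -0.55. With normexp background correction 0 genes rose and 3 fell from 30 to 36 h, 0 rose and 0 fell from 36 to 42 h, and 3 rose and 3 fell from 42 to 48 h. With slide as a block the 3 steps in turn called 26 higher and 2 lower, 1 and 0, and 525 and 53. Leaving out 1 array gave 0 to 18 higher and 0 to 16 lower from 30 to 36 h, and 0 to 65 and 0 to 41 from 36 to 42 h. From 42 to 48 h it gave 269 higher and 606 lower without 42 h replicate 3, and 0 and 0 without any 1 array of 48 h. Without 42 h replicate 3, slide 3 holds only 48 h arrays, so slide and this step cannot be told apart there. With normexp Nr1d1 stood at 0.85, Dnase1l3 at 0.54, Dclk3 at 0.14, Tmem252 at -0.40, Car5b at -0.47 and Plekhg4 at -0.36 without passing, and with slide as a block Add3 stood at -0.52 without passing. Per2 passed with normexp, at -0.67 from 30 to 36 h and 0.64 from 42 to 48 h. Fits of a single slide called 0 genes for the steps to 36 and 42 h, and 180 higher and 44 lower for the step to 48 h. Slide 1 holds 1 array of 36 h and slide 3 holds 1 array of 42 h, so values and counts there rest on that array, whose spread was taken from the other time.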

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

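The array brightness covariate and the omission of 2 arrays together were chosen after seeing the data; the other alternatives were planned. Of the named genes' values under alternatives other than leaving out 1 array, 2161 stayed on their side of the threshold, 639 lost and 64 gained a call. Another 7, called in the main fit or in the alternative, turned sign. For lists these counts were 620, 39, 11 and 2. Values called in neither fit were counted as staying whatever their sign. Below, pairs are genes higher and lower, in the order 42 h against 30 h, 48 h against 36 h, 36 h against 30 h, 42 h against 36 h and 48 h against 42 h, after the genes changed over time; the cause of each change was not tested unless stated. Normexp, whose offset of 50 draws changes of dim probes toward 0, gave 401, then 34 and 31, 120 and 145, 0 and 3, 0 and 0, 3 and 3, and moved the median of all genes by -0.12 at 48 h against 36 h. No filter gave 284, then 44 and 31, 110 and 50, 0 and 0, 2 and 0, 2 and 2. Slide as a fixed block gave 295, then 1 and 0, 520 and 44, 26 and 2, 1 and 0, 525 and 53, with 7 list shifts against 15. Slide as a random block (correlation 0.424) gave 123, then 39 and 23, 62 and 22, 3 and 3, 40 and 16, 11 and 1; camera takes no random block and was not run there. The replicate block gave 311, then 60 and 38, 164 and 83, 0 and 0, 2 and 0, 0 and 0 and changed no list call. Samples of a number had deviation correlations from -0.42 to 0.08, and 0 arrays matched their own number best. No pairing by number was seen, but slide and brightness may also enter these deviations, so a pairing is not excluded. Array quality weights gave 11191, then 2871 and 2418, 4340 and 3965, 749 and 975, 3663 and 2477, 2082 and 2944, but with weights 10 random splits called 0 to 9202 genes. A log2 change of at least 1 gave 144, then 10 and 12, 31 and 31, 0 and 3, 1 and 1, 5 and 1, and an adjusted p under 0.01 gave 226, then 39 and 29, 88 and 35, 1 and 0, 2 and 0, 0 and 0, both by construction. The 2 groups alone, with fewer arrays for the spread, gave 0 and 0, 463 and 617, 0 and 0, 4 and 1, 0 and 0. The brightness covariate gave 361, then 136 and 111, 139 and 81, 34 and 42, 64 and 37, 38 and 12. Without 36 h replicate 1 and 42 h replicate 3 together there were 4331, then 195 and 68, 2162 and 2535, 8 and 10, 5 and 4, 655 and 1480. Only these 2 arrays link the slides. Without them slide and time cannot be told apart in any contrast but 42 h against 36 h. Quantile scaling moved no count by over 1.5 times. The median shift gave 61 lower at 42 h against 30 h and 13 lower at 48 h against 42 h; probes above background on all 12 arrays gave 45 and 18 for 48 h against 42 h; the mean of all probes gave 5 higher at 36 h against 30 h and 39 higher at 48 h against 42 h; the deposited table gave 6 and 15 for 36 h against 30 h and 9 lower at 42 h against 36 h. Slides 1 and 2 alone gave 0 and 0 for their steps and slide 3 gave 180 and 44, with 1 array of 36 h on slide 1 and 1 of 42 h on slide 3. An estimated correlation left 0 list shifts. Leaving out 1 array gave 313 to 2400 genes over time, with 916 and 766 without 30 h replicate 1 and 42 h replicate 2 and the other 10 arrays each moving the count by over 1.5 times: 320 and 496 without 30 h replicates 2 and 3, 1795, 511 and 680 without 36 h replicates 1, 2 and 3, 2086 and 2400 without 42 h replicates 1 and 3, and 443, 360 and 313 without 48 h replicates 1, 2 and 3. The ranges of the pairs were 58 to 203 and 45 to 170, 93 to 1473 and 42 to 1371, 0 to 18 and 0 to 16, 0 to 65 and 0 to 41, 0 to 269 and 0 to 606, and 13 to 17 list shifts. Signs turned with normexp for Rnf152 (-0.0577) at 42 h against 30 h and Myh8 (-0.0675), Has2 (-0.09), Cd163 (-0.19), Bcl2a1 (-0.14) and Egr2 (-0.0342) at 48 h against 36 h, and with slide as a fixed block for Rax (0.32) at 48 h against 36 h and, at 42 h against 30 h, the ribosomal proteins (0.21) and leukocyte markers (-0.0941). Rnf152, Myh8, Has2, Cd163 and Bcl2a1 were not well above background at 1 or both times, which limits their values.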

Other observations

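The test of slide for the number of calls was chosen after the result was seen, as were the array brightness covariate and the genes of the first paragraph. Within the cell cycle list, the 6 replication helicase genes stood below 0 at 48 h against 36 h, where 17 other genes of the list, most of them mitotic, rose. Genes of DNA synthesis did not all go the way of the helicases, as Rrm2, among the 17, rose by 0.58. Mcm2 stood at -0.27, Mcm3 at -0.43, Mcm5 at -0.62, Mcm6 at -0.14 and Mcm7 at -0.19, and without 48 h replicate 2 Mcm6 stood at -0.03 and Mcm7 at -0.10. Mcm5 passed (adjusted p = 0.0444), a call kept in 9 of 26 alternatives, and Mcm2 and Mcm3 missed the threshold (adjusted p = 0.053 and 0.0573). Without 48 h replicate 1 Mcm6 stood at -0.23. Mcm4 stood at -0.02 and kept its sign in 19 of 26 alternatives, with values from -0.12 to 0.10. Pcna, the replication clamp, stood at -0.25 (adjusted p = 0.123) and at 0.09 with slide as a block. At 42 h against 30 h no helicase gene was called, and Mcm5, at 0.02, kept its sign in 21 of 26 alternatives. The difference between replication and mitotic genes was not tested.

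The E-box and D-box clock output list shifted down at 42 h against 30 h, where 4 of 12 genes fell and 2 stood above 0. It shifted up at 48 h against 36 h, where 4 rose and 1 stood below 0. With slide as a fixed block the list kept both directions, with medians of -0.445 and 0.569 and limma's unadjusted camera values of 0.00286 and 0.00333 (adjusted p = 0.0171 and 0.0399). By the test set beforehand this went against slide as the whole cause. That fit links the slides through 36 h replicate 1 and 42 h replicate 3 alone, however, and within slide 2 the median was 0.02 from 36 to 42 h. Each direction thus rests on 1 array, so slide is not excluded. Array brightness as the whole cause was argued against, as both directions were kept under the covariate, with unadjusted camera values of 2.86e-06 and 4.52e-06. These values assume the preset correlation between genes, and with an estimated one neither call held after adjustment. Time after synchronization, which the design names, stays open, and a rhythm may be part of it.

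The cell cycle list shifted up at 42 h against 30 h, where 15 of 38 genes rose. It also did so at 48 h against 36 h, where 17 rose, 1 fell and 11 stood below 0. Blocked on slide, the medians were 0.35 and 0.341 against 0.442 and 0.501, with limma's unadjusted camera values of 1.7e-07 and 0.00898, which argues against slide as the whole cause at 42 h (adjusted p = 4.08e-06) and less firmly at 48 h, where the call ended after adjustment over the lists (adjusted p = 0.0539) and slide stays open as a part. With the brightness covariate the unadjusted values were 1.4e-27 and 1.23e-10. An estimated correlation left neither call, so a coordinated shift of few independent genes stays open. Time in culture and the clock may each contribute and were not separated by this design.

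More genes were called at 48 h against 36 h (993) than at 42 h against 30 h (243). With slide as a fixed block 7.6% of the 993 calls were kept, as a slide effect would give, yet 991 genes kept their sign, with a median change of 0.389 against 0.466 and a median SE of 0.149 against 0.0949, and 564 genes were called against 1. The SE grew, but only 75 of the 564 blocked calls were among the 993, and a larger SE does not account for the new calls. Why the calls changed was not tested, and slide stays open as a part of the count. With the brightness covariate 19.3% were kept, with a median change of 0.365, which decides nothing. The difference between the contrasts was not tested.

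Of 100 drawn splits of the 12 arrays into 4 groups of 3, only the real split, 1 split, called as many as 1087 genes by the F-test. The highest of the other splits called 2. The draw covers a part of all such splits, and a regrouping of the 36 h and 42 h arrays called 2872 genes for that step. Chance is thus made less likely there but is not excluded. The drawn splits treat the arrays as exchangeable, whereas the real one runs nearly along the slides (correlation of arrays of a slide 0.424), so slide is not excluded. The count was 295 with slide as a fixed block and 123 as a random block. For pairs of times, 6 arrays make 10 splits, too few for a share under 0.05. At 42 h against 30 h 1 split, the real one, called 243 genes and the highest other 0, and at 48 h against 36 h 1 split called 993 and the highest other 0. At 36 h against 30 h 1 split called 10 and the highest other 1, and at 48 h against 42 h 1 split called 30 and the highest other 0. At 42 h against 36 h 2 splits called as many as the real 54. The other, with 36 h replicate 1 and 42 h replicates 2 and 3 on one side, called 2872 genes, which points to a structure of the samples. These are the 3 brightest of the 6 arrays, with 75th percentiles of log2 intensity of 9.95, 9.81 and 10.01 against 9.29 to 9.41 for the others. With the brightness covariate this step called 64 genes higher and 37 lower, and within slide 2 it called 0.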
